A study of Mus musculus with 386 samples.

How the data were processed

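Gene expression was measured on Affymetrix Mouse Gene 1.1 ST arrays in brain, kidney, liver and lung of 23-day-old mice. The mice came from 3 inbred strains, CAST, PWK and WSB, and from the 6 reciprocal F1 crosses between them, in both sexes. Crosses are named with the dam first, so CASTxPWK had a CAST dam and a PWK sire. Cross, sex, tissue and animal were read from the labels, and each replicate within a cross and tissue is a separate animal per the labels. Replicate numbers were given in the order of the records within a cross and tissue and only name an array. The arrays came from 111 animals, of which 67 gave all 4 tissues and 3 gave a single tissue. No 2 arrays held the same values, and the highest correlation between any 2 arrays was 0.9952.

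The values that the authors deposited are log2 signals per transcript cluster. The submitters' processing notes name RMA and Affymetrix Expression Console, without versions. Whether the tissues were normalised together is not given in the sources used here, and neither are plate, litter or collection day. The table held 35556 transcript clusters with 0 missing values, from 1.6 to 14.55 log2, and the median per array lay between 5.89 and 6.36. For arrays, their number limits the precision. The platform annotation paired 21218 clusters with 1 gene symbol, 1881 with several and listed none for 12457. Only clusters with 1 symbol were used, and of these 21185 matched the gene table of assembly GRCm38.p6, which served for current symbols and chromosomes only, because the annotation build of the array is not named. Of several clusters with the same symbol the one with the highest mean over all arrays was kept, which concerned 1386 of the 18820 genes. Sequence differences between the strains under the probes were not analysed here, so a strain difference in signal is not shown to be a difference in transcript amount.

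The test, samples, covariates, gene lists and alternatives of each comparison were fixed before the data were examined, except where the text says otherwise. In each tissue a gene was tested if its mean was at or above the 40th percentile of that tissue, which left 11292 genes per tissue. Tests were run with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), on a model of 18 cross-by-sex means per tissue. P-values were adjusted by the Benjamini-Hochberg method over the genes of each tissue and contrast, and genes with an adjusted p under 0.05 are referred to as called. Inbred contrasts subtract the second strain from the first, reciprocal contrasts subtract the cross with the second strain as dam from the cross with the first strain as dam, and mid-parent contrasts subtract the mean of both inbred strains from the mean of both F1 crosses. Each of these weights the sexes equally, and the sex contrast is female minus male over all 9 crosses. The tissue comparison used 36 cross-by-tissue means over all arrays and set each tissue against the mean of the other tissues. Interactions of sex with cross used an F-test with 8 degrees of freedom. Fixed before the data were examined, 58 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, where at least 5 members were tested. Lists were called at the preset correlation, and the p with an estimated correlation, or for some both, and counts of members adjusted over the list alone are given beside them.

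For each F1 animal a transmission score was computed per pair of strains, by regression of its deviation from the mid-parent value on the inbred difference over the called genes of a class. A score of 0.5 stands for the level of the first strain and -0.5 for the level of the second. Scores were made for X-linked and autosomal genes (at least 10 genes) and for listed imprinted genes expressed from the paternal or the maternal copy (at least 3 genes). Reciprocal crosses were compared within each sex by two-sided exact permutation tests, adjusted together over all tissues, pairs, classes and sexes. The position of X-linked expression in F1 females was described by the X-linked minus the autosomal score, and fry tested whether the X-linked genes of F1 females, weighted by the inbred difference, lay off the female mid-parent value. Relations between tissues of the same animals used 100000 resamples.

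The text names genes by a rule fixed in advance. For tissues these are the 3 with the highest log2 difference. For inbred, reciprocal and mid-parent contrasts they are the highest and the lowest among the called genes of each tissue and contrast. For sex they are the 3 highest and 3 lowest called genes per tissue, and Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Kdm6a, Kdm5c, Eif2s3x and Ddx3x. Of each gene list described they are up to 4 called members with the smallest p, or 2 with the smallest p if none was called. Genes named outside this rule are said to have been chosen after their values were seen.

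The alternatives tried were no filter and a filter at the 60th percentile, a renewed quantile normalisation per tissue, an additive model of cross and sex, array weights, and a random block of neighbouring animal numbers within a cross. They also included other choices of genes or weights for the scores, and leaving out in turn each of 155 arrays from cross-by-sex groups of at most 5. Runs of animal numbers had steps of at most 4 and made 25 runs over the 111 animals. Alternatives added after the data were seen were the removal of the arrays whose sex-linked genes go against the label, the removal of 3 kidney arrays with the widest residuals, 3 kinds of covariate, a mid-parent value on the linear scale, the random block for sex by cross, and all tested genes for the X position. As a check of pairing, the 4 tissues of an animal are tied by the labels, so the tissue comparison was repeated with a replicate block, the animal as a random block. It called 10892 genes in brain, 10700 in kidney, 10900 in liver and 10881 in lung, with a consensus correlation of 0.0395, and changed no count by over 1.5 times. Other groupings of the samples, up to 100 per comparison, were counted for each test across genes.

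The gene-wise fits were tested on simulated data drawn from the real means and spreads of 11292 genes per tissue, with 200 genes changed. The simulation drew on these means and spreads and not on runs of animal numbers, so false calls from a correlation within runs are not covered. In the 4 simulated contrasts (inbred CAST and PWK, reciprocal CAST and WSB, mid-parent PWK and WSB, and sex) genes changed by 0.5 log2 were recovered at 86% to 100%, genes changed by 0.25 log2 at 28% to 98%, and 3 to 15 unchanged genes were called. Other tools were the R package data.table (1.17.8), Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.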

Results

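Expression was measured in 85 brain arrays (44 from females, 41 from males), 102 kidney arrays (51 and 51), 101 liver arrays (49 and 52) and 98 lung arrays (50 and 48). The animals belonged to 9 crosses, which were the 3 inbred strains and the 6 reciprocal F1 crosses between them, with 11 to 13 animals per cross. Each cross and tissue had 6 to 13 arrays and each cross, sex and tissue 2 to 7. All values are log2 signals and all differences are on the log2 scale. The design allows comparisons between tissues, between strains, between reciprocal crosses, between F1 animals and their inbred parents, and between the sexes.

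The tissues differed in the genes of their main cell types. In brain, Snap25, a component of the machinery of synaptic vesicle release, stood at 12.97 ± 0.08 (SD, n = 85). It was 7.33 ± 0.06 (SE) above the mean of the other tissues, followed by Cplx1 (7.22 ± 0.04), another synaptic gene, and the neuronal kinesin gene Kif5a (7.16 ± 0.03). Kidney was highest over the other tissues for Mep1a (8.21 ± 0.06), a brush-border protease, Umod (8.07 ± 0.07), which encodes uromodulin, and the tubular transporter Slc5a12 (7.92 ± 0.06). Liver was highest for Ugt2b1 (7.88 ± 0.10), Akr1c6 (7.61 ± 0.06) and Gulo (7.56 ± 0.08), which encodes the last enzyme of vitamin C synthesis. Lung was highest for the surfactant protein genes Sftpc (7.96 ± 0.08), Sftpa1 (7.83 ± 0.03) and Sftpb (7.77 ± 0.03). By groups, 11 of 11 neuron markers were highest in brain and 14 of 14 hepatocyte markers in liver. So were 11 of 11 proximal tubule markers in kidney and 11 of 12 alveolar markers in lung. Markers of neighbouring tissues were measured too: 8 of 9 heart muscle markers were highest in lung, with a median level of 10.82, and 5 of 8 brown fat markers were highest in kidney, with a median of 9.82. With limma, 10886 genes were called in brain, 10691 in kidney, 10890 in liver and 10872 in lung of 11292 tested. Of these, 1890, 1395, 1448 and 1934 were higher by at least 1 log2 unit and 2576, 1141, 2523 and 1407 lower. Without the filter on low signals 17486, 16621, 18011 and 17909 genes were called.

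Xist, the RNA that coats the inactive X chromosome, and the Y-linked gene Eif2s3y were set against the sex labels of all arrays. Xist was higher in females by 5.92 ± 0.16 (SE) in brain, 6.10 ± 0.07 in kidney, 6.59 ± 0.14 in liver and 6.99 ± 0.08 in lung. On 2 arrays the genes went against the label. The brain array of PWKxCAST replicate 9, labelled female, had Xist at 3.98 and Eif2s3y at 3.83. The liver array of PWKxWSB replicate 8, labelled male, had Xist at 10.70 and Eif2s3y at 4.53, while kidney and lung of the same animal had Xist at 4.05 and 3.78 and Eif2s3y at 8.67 and 8.50. Both arrays stayed in their labelled groups.

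**Figure D1:**
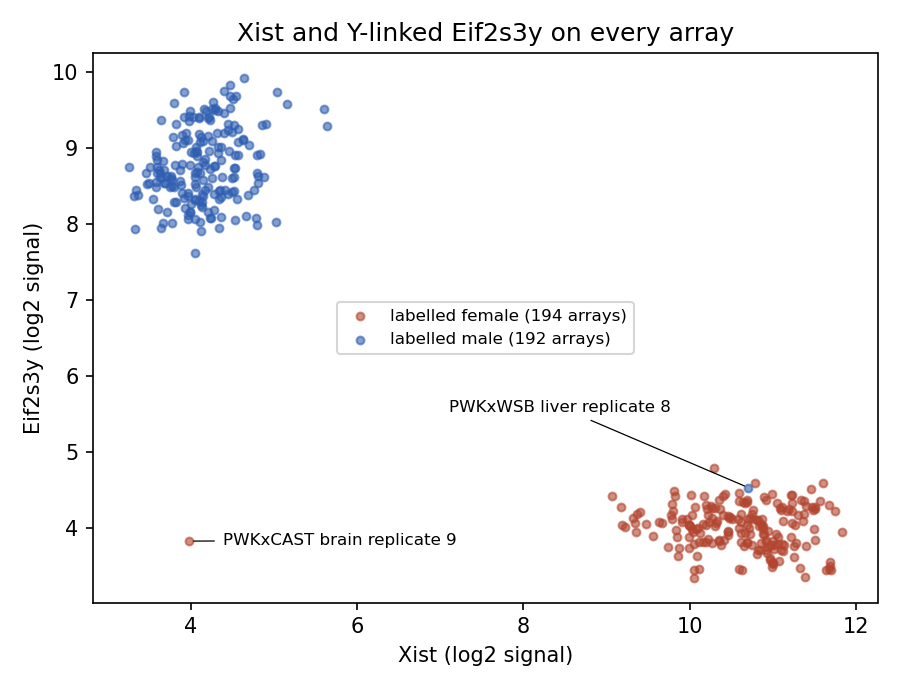
Xist against Eif2s3y signal (both log2) on all arrays, 194 labelled female and 192 labelled male, one point per array. PWKxCAST brain replicate 9 lies low on both axes (3.98 and 3.83) and PWKxWSB liver replicate 8, labelled male, lies among the females on the Xist axis (10.70).

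The sexes differed in liver, kidney and lung genes beyond the sex chromosomes, and in brain by few genes. In liver, Cyp3a16, a cytochrome P450 gene, was higher in females by 2.32 ± 0.12 (SE), at 9.63 ± 1.08 (SD, n = 49) against 7.37 ± 1.89 (SD, n = 52). Cyp2b13 was higher by 1.95 ± 0.14. In kidney, A2m, which encodes a protease inhibitor, was higher in females by 1.51 ± 0.13, at 7.38 ± 1.46 (SD, n = 51) against 5.83 ± 0.63 (SD, n = 51). Ly6f was higher by 1.48 ± 0.13, while the transporter gene Slc22a30 differed by -1.13 ± 0.12. In lung, after Xist, Kdm6a (0.59 ± 0.02) and Eif2s3x (0.49 ± 0.02) were highest in females and Col6a5 (-0.34 ± 0.04), Per2 (-0.31 ± 0.08) and Crispld2 (-0.28 ± 0.05) lowest. Per2, a circadian clock gene, had an adjusted p = 0.0269, and its call ended without PWKxWSB lung replicate 9 (adjusted p = 0.0537), with runs of animal numbers as a random block (0.102) and with a covariate of lymphocyte markers (0.174). In brain, Tceal6, an X-linked gene, was higher in females by 0.76 ± 0.09, and its call ended in the additive model (adjusted p = 0.127). The Y-linked genes passed the filter on low signals in part: Eif2s3y differed by -4.57 ± 0.05 in kidney and -5.08 ± 0.10 in liver, Kdm5d by -3.74 ± 0.05 and -3.62 ± 0.10, and Uty by -4.91 ± 0.10 in liver. Ddx3y was tested in no tissue. Of the X-linked genes known to escape X inactivation, 4 were higher in females in every tissue. In brain, kidney, liver and lung Kdm6a differed by 0.34, 0.59, 0.57 and 0.59 and Eif2s3x by 0.46, 0.37, 0.40 and 0.49. Kdm5c differed by 0.30, 0.33, 0.38 and 0.40 and Ddx3x by 0.30, 0.13, 0.28 and 0.32.

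Lists of genes known to depend on sex in adults moved in liver and kidney. All 17 tested genes of the adult male-biased list were lower in females (17 adjusted over the list alone, adjusted p = 7.2e-48 with camera and 1.05e-06 with an estimated correlation). Among them were Elovl3, a fatty acid elongase gene (-1.72), Cyp2d9 (-0.75), Cyp4a12a (-1.44) and the complement gene C6 (-0.58). Of the adult female-biased list 16 of 18 were higher in females (17 adjusted over the list alone, adjusted p = 2e-46, and 7.3e-10 with an estimated correlation). Among them were Cyp17a1 (1.10) and Cyp2b9 (1.23). In kidney the androgen-response list had 8 lower and 2 higher of 15 (11 adjusted over the list alone, adjusted p = 4.31e-06, and 0.0113 with an estimated correlation). Slc7a13 was at 10.23 ± 0.36 in females and 10.81 ± 0.40 in males (SD, n = 51 each), and Cyp4b1 differed by -0.65. Of 6 tested neuropeptide and dopamine genes in kidney 3 were higher in females (3 adjusted over the list alone, adjusted p = 0.00918 with an estimated correlation), among them Ddc (0.15) and Npy (0.30). In liver the androgen-response list of kidney had 8 lower and 1 higher of 14 (10 adjusted over the list alone, adjusted p = 0.000126 with an estimated correlation). The list of X-escape genes shifted up in females in each tissue, with 4 of 7 higher in brain, kidney and liver and 5 of 7 in lung, where 1 was lower (5, 4, 5 and 6 adjusted over the list alone). In brain, kidney, liver and lung the adjusted p-values were 1.22e-31, 3.09e-13, 1.51e-15 and 2.99e-23 with camera, and 1.88e-17, 1.93e-07, 1.53e-07 and 6.18e-12 with an estimated correlation. Proliferation genes were lower in females in kidney (21 of 21, 21 adjusted over the list alone, median -0.27) and liver (21 of 24, 23 adjusted over the list alone, median -0.50). Examples were Kif11 at -0.40 in kidney and Cdc20 at -0.79 in liver. These list calls were lost with an estimated correlation, with adjusted p = 0.173 and adjusted p = 0.12. In lung, 8 of 28 genes of extracellular matrix were lower in females (17 adjusted over the list alone), among them Col1a2 (-0.18) and Col1a1 (-0.20). The list had adjusted p = 0.139 with an estimated correlation.

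Over all genes, 8 were called between the sexes in brain (903 at an unadjusted p under 0.05), 1234 in kidney (553 higher in females, 681 lower), 1554 in liver (989 and 565) and 397 in lung (253 and 144) with limma. With runs of animal numbers as a random block the counts were 757 in kidney and 179 in lung, and with array weights 17 in brain, 2088 in kidney and 1028 in lung. Covariates chosen after the data were seen gave 991 in liver (other-tissue markers) and 127 in lung (lymphocytes). Leaving out single arrays moved the lung count to between 189 (without CASTxPWK lung replicate 4) and 817 (without WSBxWSB lung replicate 11). It was 240 without CASTxCAST lung replicate 2 or CASTxWSB lung replicate 7, 603 without PWKxWSB lung replicate 2, 211 without PWKxWSB lung replicate 9 and 260 without WSBxWSB lung replicate 1. The sex difference itself depended on the cross for 80 genes in brain, 510 in kidney, 918 in liver and 2630 in lung in the interaction test. With runs of animal numbers as a random block, chosen for this test after the data were seen, the counts were 26, 205, 196 and 155, and in CASTxCAST no run held both sexes, so that sex and run cannot be told apart there.

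The inbred strains were compared within each tissue. In lung, Chil3, a chitinase-like gene of macrophages, was higher in CAST than in PWK by 7.52 ± 0.15 (SE), at 10.95 ± 0.30 (SD, n = 10) against 3.42 ± 0.33 (SD, n = 12). Chia1, an acidic chitinase gene, differed by -6.96 ± 0.09 between CAST and PWK and by -6.30 ± 0.09 between CAST and WSB. The class II genes H2-Eb1 (CAST over WSB by 4.65 ± 0.10) and H2-Ea (PWK below WSB, -6.27 ± 0.08) and the gene Nell1 (PWK over WSB by 5.38 ± 0.08) were the other extremes in lung. In liver, Gsdma3 was higher in CAST than in PWK by 5.97 ± 0.09 and Rarres1 lower (-6.99 ± 0.07). Hsd3b5, a steroid dehydrogenase gene, was lower in WSB than in CAST, at 4.90 ± 1.41 (SD, n = 13) against 11.28 ± 0.49 (SD, n = 11). It was also lower than in PWK (a difference of 6.77 ± 0.24). Cyp2b13 was higher in WSB than in CAST (-6.81 ± 0.30), and the acute-phase gene Orm1 higher in WSB than in PWK (-6.53 ± 0.16). In kidney, Tm4sf5 was lower in WSB, at 5.61 ± 0.94 (SD, n = 12), than in CAST (a difference of 6.37 ± 0.15) and PWK (6.02 ± 0.14). Sycn (-6.28 ± 0.10) and Spink1 (-6.05 ± 0.09), both genes of the exocrine pancreas, were higher in WSB than in CAST and in PWK. Sectm1b (4.58 ± 0.11) and the transporter gene Slc22a22 (-5.38 ± 0.14) were the extremes between CAST and PWK.

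In brain, Lyz2, the lysozyme gene of myeloid cells, was higher in CAST than in PWK by 2.73 ± 0.22 (SE), at 7.41 ± 0.46 (SD, n = 8) against 4.76 ± 0.35 (SD, n = 6). Tceal6 was lower (-3.83 ± 0.21). Retsat, which encodes retinol saturase, was higher in CAST than in WSB by 2.36 ± 0.06 and 1700048O20Rik lower (-3.63 ± 0.20). Acy3 was higher in PWK than in WSB by 2.35 ± 0.09 and 2610524H06Rik lower (-4.98 ± 0.11). With limma, 4615, 5915 and 4562 genes were called in brain between CAST and PWK, CAST and WSB, and PWK and WSB. In the same order there were 6790, 6734 and 6853 in kidney, 5657, 6437 and 6249 in liver and 7075, 6764 and 6935 in lung. Those at least 1 log2 unit apart numbered, as higher and lower in the first strain, 65 and 91, 70 and 80, and 64 and 80 in brain. They numbered 159 and 210, 164 and 225, and 200 and 209 in kidney. In liver they numbered 215 and 272, 231 and 299, and 249 and 257, and in lung 286 and 224, 211 and 187, and 223 and 222. Sequence differences under the probes were not analysed here, and they would be counted among these genes.

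Several gene lists moved between the strains. In liver, 14 of 21 acute-phase genes were lower and 2 higher in CAST than in WSB (16 adjusted over the list alone, median -1.09, adjusted p = 5.64e-08, and 0.0384 with an estimated correlation). Lcn2 was at 7.50 ± 0.41 (SD, n = 11) against 11.68 ± 0.32 (SD, n = 13), and Orm3 differed by -4.11 and Saa4 by -1.95. This was the only list call between inbred strains that held with an estimated correlation, of 10 calls in brain, 6 in kidney, 20 in liver and 7 in lung. Interferon-response genes were lower in CAST liver than in PWK (19 of 23, with 2 higher, 21 adjusted over the list alone, adjusted p = 0.452 with an estimated correlation). So they were against WSB (19 of 23, with 1 higher, 21 adjusted over the list alone, adjusted p = 0.0922 with an estimated correlation). Against PWK, Iigp1 differed by -6.18 and Usp18 by -2.47, while Ifi27 was higher in CAST by 2.6. Cholesterol synthesis genes were lower in CAST than in PWK in liver (17 of 19, 17 adjusted over the list alone) and brain (13 of 19, with 1 higher, 14 adjusted over the list alone). These had adjusted p = 0.762 and adjusted p = 0.993 with an estimated correlation. Immediate-early genes, which respond to neuronal activity, were lower in CAST than in PWK brain (15 of 21, 16 adjusted over the list alone), with Arc at -1.54 and Fos at -1.0. These genes had adjusted p = 0.993 with an estimated correlation. Matrix genes were higher in PWK than in WSB kidney (24 of 28, with 1 lower, 25 adjusted over the list alone), with Col5a2 at 1.69. The list had adjusted p = 0.733 with an estimated correlation. Heart muscle genes were lower in PWK than in WSB lung (8 of 8, 8 adjusted over the list alone), with Actc1 at -0.66 and Myl7 at -1.45. These genes had adjusted p = 0.956 with an estimated correlation.

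Of the 9152 genes tested in all 4 tissues, 1061 were called in the same direction in all of them between CAST and PWK, 1201 between CAST and WSB and 1111 between PWK and WSB, where independent lists would share 82, 128 and 105. Between 2 tissues the shared calls were a median of 1.84, 1.76 and 1.82 times those of independent lists. For calls of at least 1 log2 unit the medians were 21.53, 24.85 and 22.60 times. The tissues came from the same mice, and a sequence difference under a probe would give the same direction in each tissue.

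Reciprocal F1 crosses carry the same autosomal genotypes and differ in the dam. X-linked and imprinted genes were among those with the widest differences. Tceal6, an X-linked gene, was lower in CASTxPWK than in PWKxCAST brain (-2.35 ± 0.17, SE), at 7.21 ± 1.92 (SD, n = 10) against 9.51 ± 0.47 (SD, n = 10). It was also lower in CASTxWSB than in WSBxCAST brain (-2.15 ± 0.18). Xpnpep2, an X-linked aminopeptidase gene, was higher in CASTxPWK than in PWKxCAST lung by 2.09 ± 0.07, and Mest, an imprinted gene expressed from the paternal copy, lower (-0.80 ± 0.08). In kidney the X-linked genes Nudt10 (CASTxWSB below WSBxCAST, -1.27 ± 0.16) and Kcne1l (PWKxWSB below WSBxPWK, -1.58 ± 0.11) were the lowest. In liver Mir675, the microRNA gene within the imprinted H19, was lower in CASTxPWK than in PWKxCAST (-1.95 ± 0.27). It was higher in PWKxWSB than in WSBxPWK by 3.24 ± 0.26, at 10.99 ± 1.32 (SD, n = 12) against 7.75 ± 0.70 (SD, n = 12). Gm26504 was lower in CASTxWSB than in WSBxCAST liver (-1.25 ± 0.21) and lung (-1.15 ± 0.19) and in PWKxWSB than in WSBxPWK liver (-1.56 ± 0.21). Dlk1, another imprinted gene expressed from the paternal copy, was higher in PWKxWSB than in WSBxPWK lung by 1.31 ± 0.15, at 7.82 ± 0.33 (SD, n = 10) against 6.55 ± 0.23 (SD, n = 11).

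In brain the X-linked genes Uprt (0.58, CAST and PWK), Ndufa1 (0.51) and Firre (-0.62, both PWK and WSB) and the autosomal Plekhf1 (0.86, CAST and WSB) were the other extremes. With runs of neighbouring animal numbers as a random block Uprt (adjusted p = 0.00188) and Plekhf1 (0.0361) stayed called, and Ndufa1 (0.479) and Firre (0.0978) did not. Firre was also not called in the additive model (adjusted p = 0.0527), and Ndufa1 not without PWKxWSB brain replicate 1 (0.103), 3 (0.0586), 4 (0.0851) or 5 (0.0757). In kidney, Akr1c18 (1.77, adjusted p = 0.999 under the block), Rdh12 (-1.0, 0.496), Plk3 (1.45, 0.645) and Etnppl (0.59, 0.994) lost the call, Etnppl also without WSBxPWK kidney replicate 10 (adjusted p = 0.0636). In liver these were Tff3, a trefoil factor gene (1.54, 0.201), and Ppp1r3g, a regulator of glycogen synthesis (2.19, 0.244). In lung it was Ms4a1, which encodes the B cell antigen CD20 (PWK and WSB, -1.13, 0.0965). The differences under the block were of similar size, at 0.48 for Ndufa1, -0.63 for Firre, 1.73 for Akr1c18, -0.92 for Rdh12, 1.37 for Plk3, 0.57 for Etnppl, 1.53 for Tff3, 1.97 for Ppp1r3g and -1.30 for Ms4a1. Fkbp5, a target gene of the glucocorticoid receptor, was higher in CASTxWSB than in WSBxCAST lung by 1.47 ± 0.33 (SE), at 9.17 ± 0.73 (SD, n = 11) against 7.70 ± 0.62 (SD, n = 12). Its difference was 0.46 (adjusted p = 0.0745) with the glucocorticoid target level of the other tissues as a covariate and 0.30 (adjusted p = 0.574) with a lymphocyte covariate. The first covariate also ended the calls of Plekhf1 (0.34, adjusted p = 0.631) and Plk3 (0.55, adjusted p = 0.336), and the lymphocyte covariate that of Ms4a1 (-0.28, adjusted p = 0.311).

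With limma, 17, 88 and 28 genes were called in brain between the reciprocal crosses of CAST and PWK, CAST and WSB, and PWK and WSB. In the same order there were 342, 275 and 113 in kidney, 1052, 635 and 138 in liver, and 69, 4381 and 949 in lung. With runs of animal numbers as a random block the counts were 6, 15 and 5 in brain, 5, 7 and 4 in kidney, 10, 38 and 5 in liver, and 8, 1099 and 24 in lung. With array weights, in place of the block, they were 72, 481 and 388 in brain, 2285, 1211 and 483 in liver, 773 and 230 in kidney and 421 and 1568 in lung (first and last pair in the last 2 tissues). With the glucocorticoid covariate, chosen after the data were seen, those for CAST and WSB were 9, 73, 295 and 2731 in brain, kidney, liver and lung, and with the lymphocyte covariate the lung counts were 133, 179 and 122. The consensus correlations of the block were 0.0876, 0.256, 0.213 and 0.213 in the 4 tissues. X-linked genes made up 12 of the 17 genes called in brain between the CAST and PWK crosses, 41 of 342 in kidney, 65 of 1052 in liver and 28 of 69 in lung. Under the block they made up 6 of 6, 4 of 5, 7 of 10 and 6 of 8. For PWK and WSB X-linked genes made up 4 of 5, 4 of 4, 2 of 5 and 14 of 24 under the block. For CAST and WSB they made up 6 of 15, 4 of 7, 8 of 38 and 72 of 1099 under the block. Of these 1099 genes in lung, 1016 were neither X-linked nor among the listed imprinted genes. The genes of the counts of 5 or fewer under the block were named after their values were seen. For PWK and WSB in brain they were the X-linked Phka2 (-0.40), Apln (-0.47), Rpl39 (-0.43) and Dcaf12l1 (-0.43) and the imprinted growth factor gene Igf2 (-0.49). For CAST and PWK in kidney they were the X-linked 1810030O07Rik (-0.55), Heph (-0.48), Mid1 (-0.73) and Sytl4 (-0.58) and the imprinted gene Grb10 (0.32), and for PWK and WSB in kidney the X-linked Kcne1l (-1.55), Rpl39 (-0.46), Glod5 (-0.97) and Apln (-0.57). For PWK and WSB in liver they were Mir675 (3.34), Igf2 (-1.26), Gm26504 (-1.56) and the X-linked Gla (0.37) and Mpp1 (-0.48).

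Leaving out single arrays moved reciprocal counts in brain, kidney and lung. In brain the count for CAST and PWK ranged from 10 (without CASTxPWK replicate 6) to 19 (CASTxPWK replicate 4), with 11 without CASTxPWK replicate 1. That for CAST and WSB ranged from 29 (CASTxWSB replicate 5) to 122 (CASTxWSB replicate 8), with 38, 48 and 46 without CASTxWSB replicates 1, 4 and 7 and 55 and 58 without WSBxCAST replicates 4 and 8. For PWK and WSB it ranged in brain from 13 (PWKxWSB replicate 5) to 65 (PWKxWSB replicate 6), with 16, 15 and 15 without PWKxWSB replicates 3, 4 and 7. In kidney it ranged from 69 (WSBxPWK replicate 3) to 174 (WSBxPWK replicate 8), with 70 without WSBxPWK replicate 5. In lung it ranged from 227 (PWKxWSB replicate 9) to 1521 (PWKxWSB replicate 8), with 424 without PWKxWSB replicate 1 and 296 without WSBxPWK replicate 10.

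**Figure D2:**
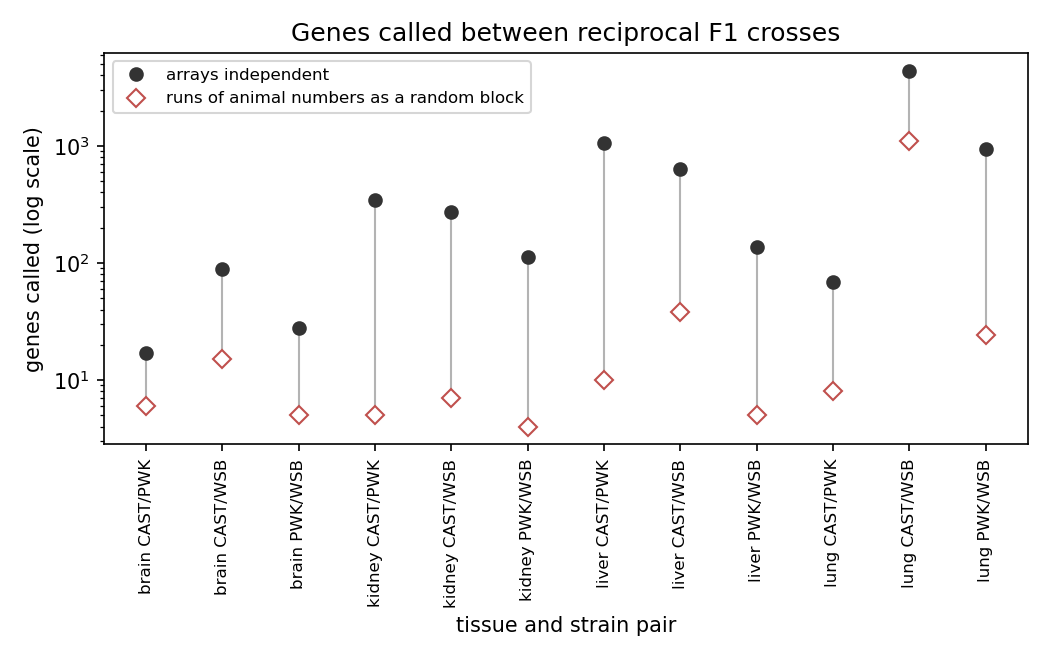
Number of genes called between reciprocal crosses (log scale) per tissue and pair of strains, with arrays taken as independent and with runs of neighbouring animal numbers as a random block. Each of the 12 counts is lower with the block, such as 1052 against 10 in liver for CAST and PWK and 4381 against 1099 in lung for CAST and WSB.

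Gene lists moved between reciprocal crosses in lung. In CASTxWSB against WSBxCAST, 8 of 9 tested T and B cell markers were lower (8 adjusted over the list alone, median -0.62). The B cell receptor gene Cd79b was at 9.32 ± 0.41 (SD, n = 11) against 10.23 ± 0.31 (SD, n = 12), and Cd79a differed by -1.06, Ms4a1 by -1.09 and the T cell receptor gene Cd3g by -0.62. These markers had adjusted p = 0.00134 with camera and adjusted p = 0.514 with an estimated correlation. Class II antigen presentation genes were lower in 8 of 8 (8 adjusted over the list alone), with H2-Aa at -0.41. Cholesterol synthesis genes were lower in 13 of 19 (16 adjusted over the list alone), with Insig1 at -0.34. Matrix genes were higher in 15 of 28 and lower in 1 (19 adjusted over the list alone), with Col5a1 at 0.36. With an estimated correlation these had adjusted p = 0.45, 0.514 and 0.514. Of 8 glucocorticoid target genes, a list chosen after the data were seen, 6 were higher in the same contrast in lung (median 0.43, p = 6.83e-05 with camera and p = 0.0771 with an estimated correlation). The list call that held in lung was that of imprinted genes expressed from the paternal copy between PWKxWSB and WSBxPWK. Of these, 6 of 19 were higher and 1 lower (9 adjusted over the list alone, median 0.03, mean 0.18, adjusted p = 0.00174 with an estimated correlation). Plagl1 was at 10.56 ± 0.15 (SD, n = 10) against 9.68 ± 0.08 (SD, n = 11), and Dlk1 differed by 1.31, Mest by 0.43 and Ndn by -0.47. In liver the list shifted the other way in this contrast, with 3 of 20 lower (4 adjusted over the list alone, adjusted p = 0.00747 with camera and adjusted p = 0.0938 with an estimated correlation). These were Igf2 (-1.39), Plagl1 (-0.45) and Sgce (-0.41).

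In the other tissues 1 list call each held with an estimated correlation between reciprocal crosses, for arrays taken as independent. Lists were not tested with runs of animal numbers as a block. In liver, 4 of 15 genes of gluconeogenesis and glycolysis were higher in CASTxWSB than in WSBxCAST (7 adjusted over the list alone, adjusted p = 0.0428 with an estimated correlation). Pck1, the gene of a rate-limiting enzyme of gluconeogenesis, was at 12.79 ± 0.13 (SD, n = 12) against 12.34 ± 0.34 (SD, n = 11), and Ppargc1a differed by 0.76 and Foxo1 by 0.59. In kidney, 3 of 7 podocyte markers were higher in PWKxWSB than in WSBxPWK (5 adjusted over the list alone, adjusted p = 0.0148 with an estimated correlation). Wt1 differed by 0.34 and Podxl by 0.20. Lists of other cell types were called in this contrast at the preset correlation with no member called, with medians of 0.10 for the distal nephron and collecting duct, 0.46 for hepatocytes, -0.17 for macrophages, -0.20 for oligodendrocytes and -0.28 for white fat. Their adjusted p was 0.118, 0.657, 0.497, 0.18 and 0.539 with an estimated correlation. Under the block the 4 genes called in this contrast and the 38 called in the liver contrast included no podocyte or gluconeogenesis and glycolysis list member. In brain, the X-escape list shifted down in CASTxWSB against WSBxCAST, with 1 of 7 lower (2 adjusted over the list alone, adjusted p = 0.0103 with an estimated correlation). The gene was Mid1 (-0.81), which stayed called under the block (-0.79, adjusted p = 8.45e-05). Kidney heat shock genes were higher in CASTxWSB (5 of 20, 8 adjusted over the list alone), with Dnajb1 at 0.57 and Hspb1 at 0.51. The list had adjusted p = 0.195 with an estimated correlation. In all, 14 list calls in brain, 30 in kidney, 27 in liver and 41 in lung were made at the preset correlation.

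Within the sexes, reciprocal crosses of females had 0, 2 and 0 genes called in brain with limma (349, 887 and 1282 at an unadjusted p under 0.05). There were 8, 0 and 0 in kidney (739, 612 and 1186), 2, 23 and 25 in liver and 3, 36 and 57 in lung. Those of males had 22, 29 and 17 in brain, 297, 189 and 99 in kidney, 277, 601 and 103 in liver and 56, 3481 and 215 in lung. The difference between the sexes was itself called for 6, 3 and 5 genes in brain, 14, 9 and 29 in kidney, 11, 11 and 12 in liver, and 12, 13 and 21 in lung. Under the random block male counts were 38, 22 and 17 in kidney, 45, 101 and 11 in liver and 26, 1623 and 40 in lung. Female counts were 0, 0 and 3 in liver and 1, 2 and 2 in lung. In kidney the count of 8 in females was 0 under the block and 0 without the filter. Without the liver array of PWKxWSB replicate 8 the liver interaction for PWK and WSB had 33 genes in place of 12.

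X-linked genes of F1 males, whose X chromosome comes from the dam, had levels nearer to the strain of the dam. The score was higher in the cross with the first strain as dam in all 12 comparisons, by 0.395 to 0.697 over 127 to 200 genes, and 11 of these had an adjusted p under 0.05 in the exact permutation test. In PWKxWSB kidney the male score was 0.333 ± 0.0365 (SD, n = 6) against -0.364 ± 0.0674 (SD, n = 5) in WSBxPWK (difference 0.697, exact p = 0.00433, adjusted p = 0.0244). In CASTxPWK kidney it was 0.0979 ± 0.101 (SD, n = 6) against -0.338 ± 0.136 (SD, n = 6) in PWKxCAST (difference 0.436, exact p = 0.00216). The exception was CAST and WSB in brain, with 0.284 ± 0.124 (SD, n = 3) against -0.346 ± 0.0527 (SD, n = 6), exact p = 0.0238 and adjusted p = 0.0629, where 0.0238 is the smallest p that these numbers of arrays allow. In F1 females the difference was -0.00478 to 0.139, with adjusted p-values of 0.0629 to 0.957 in exact permutation tests. The lowest male difference, 0.395 for PWK and WSB in liver, included the array of PWKxWSB replicate 8 with female-like sex-linked genes, and without it the lowest was 0.436. With weights from the other tissues all 12 male differences were above 0 (0.0983 to 0.731) and 7 were called. Without genes of an inbred difference of at least 2 log2 units they were 0.411 to 0.651 and 8 were called, and the 3 that lost the call had an adjusted p = 0.0525 in the exact test, with differences of 0.473, 0.411 and 0.625.

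**Figure D3:**
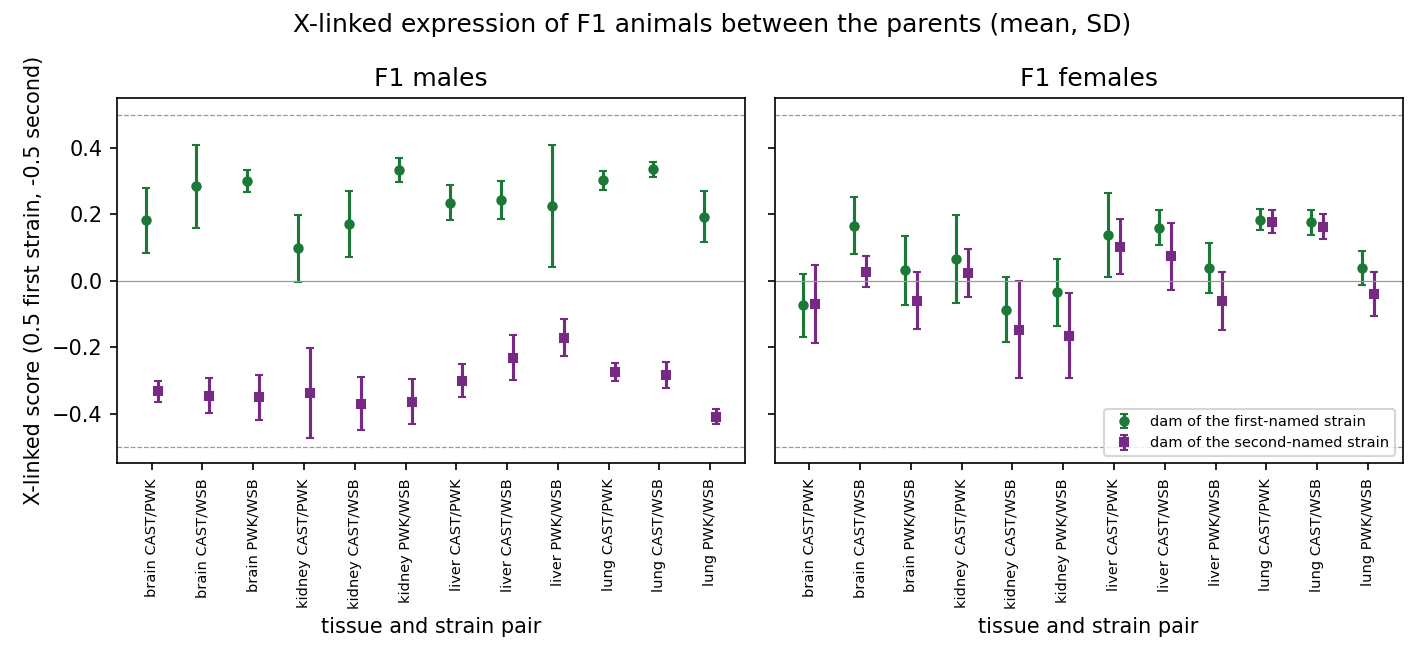
Transmission score over X-linked genes of F1 males and females, per tissue and pair of strains, as mean and SD, where 0.5 stands for the first and -0.5 for the second inbred strain (dashed lines). Male scores of the reciprocal crosses lie apart by 0.395 to 0.697 and female scores by -0.00478 to 0.139.

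Scores of listed imprinted genes were compared between the reciprocal crosses, with 5 to 14 genes per score for paternal and 4 to 16 for maternal expression. Genes expressed from the paternal copy had scores nearer to the sire in 8 of 12 comparisons of males and 6 of 12 of females that passed the exact permutation test after adjustment. In lung for CAST and WSB the score differed by -0.693 in males and -0.472 in females, while the highest differences, not called, were 0.307 and 0.127. Genes expressed from the maternal copy had scores nearer to the dam in 4 of 12 comparisons of females and 1 of 12 of males that passed, such as 0.436 in brain of CAST and PWK females (exact permutation p = 0.00433, adjusted p = 0.0244). The others were not called, with values down to -0.135 in females and -0.141 in males. Autosomal genes outside these lists passed in 1 of 12 comparisons of males and 0 of 12 of females. With weights from the other tissues genes expressed from the paternal copy passed in 2 of 12 comparisons of males and 3 of 12 of females, of which 1 went toward the dam, and genes expressed from the maternal copy in 1 of females and 2 of males. Without genes of an inbred difference of at least 2 log2 units, genes expressed from the paternal copy passed in 4 of 12 comparisons of males.

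X-linked genes of F1 females did not lie midway between the parents in each tissue. In lung they were nearer to CAST. The X-linked minus autosomal score was 0.192 ± 0.0406 (SD, n = 11, all 11 positive) for CAST and PWK and 0.217 ± 0.0375 (SD, n = 12, all 12 positive) for CAST and WSB. PWK and WSB gave 0.0184 ± 0.0585 (SD, n = 12). In liver it was 0.130 ± 0.105 (SD, n = 10) and 0.125 ± 0.0868 (SD, n = 11) for the pairs with CAST and -0.00354 ± 0.0784 (SD, n = 12) for PWK and WSB. In kidney the values were 0.0849 ± 0.0786 (SD, n = 11), -0.0566 ± 0.0963 (SD, n = 12) and -0.0862 ± 0.0999 (SD, n = 11). In brain they were -0.0309 ± 0.0983 (SD, n = 11), 0.0814 ± 0.0942 (SD, n = 10) and -0.0156 ± 0.0927 (SD, n = 11). The difference from autosomal genes itself was not tested. Fry tested whether the X-linked genes alone lay off the female mid-parent value. Its adjusted p was 1.7e-17 and 7.62e-13 in lung and 6e-05 and 0.00104 in liver for the pairs with CAST, and 0.835 and 0.991 for PWK and WSB. In kidney it was 0.241, 0.0288 and 0.0154, and in brain 0.00581 for CAST and WSB and 0.991 for the others. Without PWKxCAST brain replicate 9, whose Xist was low, the first brain value was -0.00618. With weights from the other tissues the difference from autosomal genes was -0.0933 in kidney for CAST and WSB, 0.0707 in kidney for CAST and PWK and -0.085 in lung for PWK and WSB, where it turned in direction. The adjusted p of fry for the X-linked genes alone was then 0.0605, 0.00308 and 0.00237. Without genes of an inbred difference of at least 2 log2 units the difference was -0.0554 in kidney for PWK and WSB and 0.127 in brain for CAST and PWK, where it turned in direction, with adjusted p-values of fry of 0.116 and 0.0494.

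F1 animals were compared with the mean of their parents. For several genes with the widest differences 1 parent was low and the F1 lay near the other. In liver, Mup3, a major urinary protein gene, was above the mid-parent value of CAST and PWK by 3.20 ± 0.16 (SE). It stood at 11.83 ± 0.45 in the F1 (SD, n = 21) against 10.99 ± 1.34 in CAST (SD, n = 11) and 6.28 ± 0.62 in PWK (SD, n = 9). Hsd3b5 was above it by 3.20 ± 0.16 for CAST and WSB. Ces4a, a carboxylesterase gene, was above it by 2.91 ± 0.15 for PWK and WSB, at 10.03 ± 0.51 in the F1 (SD, n = 24) against 5.67 ± 0.40 (SD, n = 9) and 8.57 ± 0.98 (SD, n = 13). Cyp2b10, a xenobiotic response gene, lay below the mid-parent value for CAST and PWK (-1.62 ± 0.23) and CAST and WSB (-2.07 ± 0.21), and Mir675 for PWK and WSB (-1.39 ± 0.19). In kidney, Pvalb (2.09 ± 0.12) and Tm4sf5 (2.74 ± 0.11 and 2.37 ± 0.10) were the highest. Bhmt, a gene of methionine metabolism (-1.25 ± 0.13), and Zbtb16, a glucocorticoid target (-1.10 ± 0.27 and -1.40 ± 0.27), were the lowest. In lung H2-Ea was above the mid-parent value for both pairs with PWK (2.56 ± 0.06 and 2.50 ± 0.06), as was Chia1 for CAST and WSB (2.13 ± 0.06). Retnla was below it for CAST and PWK (-1.42 ± 0.22). Zbtb16 (-0.99 ± 0.33) and Atp2a1 (-1.20 ± 0.46), a calcium pump gene of skeletal muscle, were the other lowest. In brain, Nkain2 (1.02 ± 0.04), Egr2 (1.18 ± 0.12), an immediate-early transcription factor gene, and 2610524H06Rik (1.51 ± 0.07) were the highest. Alas2, the heme synthesis gene of red cells (-0.64 ± 0.11), Zbtb16 (-0.59 ± 0.07) and Snord53 (-0.68 ± 0.18) were the lowest.

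Some of these calls were lost in other settings. With the mid-parent value taken on the linear scale, chosen after the data were seen, 10 of the 24 named differences moved by more than 1.5 times. Chia1 (-0.04, adjusted p = 0.723), 2610524H06Rik (-0.02, adjusted p = 0.899) and H2-Ea for CAST and PWK (0.17, adjusted p = 0.109) were then no longer called, Chia1 and 2610524H06Rik with the direction turned. H2-Ea for PWK and WSB was 0.34, Tm4sf5 0.54 and 0.33, Pvalb 0.43, Nkain2 0.55, Hsd3b5 0.99 and Mup3 1.85, all still called. Under the random block the calls of Zbtb16 in kidney for CAST and PWK (-0.96, adjusted p = 0.0608) and in lung (-0.78, adjusted p = 0.248) and of Atp2a1 (-1.26, adjusted p = 0.176) ended. That of Zbtb16 in lung also ended with a glucocorticoid (-0.16, adjusted p = 0.664) or lymphocyte covariate (-0.30, adjusted p = 0.46). Snord53 was not called with other-tissue marker covariates (adjusted p = 0.0794). Atp2a1 (adjusted p = 0.0354) varied widely, at 7.89 ± 2.62 in CAST lungs, and was not called with array weights (-1.03, adjusted p = 0.0522). Leaving out single lung arrays also ended its call, namely CASTxCAST replicate 2 (0.0875) or 4 (0.111), CASTxWSB replicate 1 (0.0544), 2 (0.0518), 3 (0.0516) or 4 (0.0502), or WSBxWSB replicate 9 (0.0927), where each value in parentheses is the adjusted p without that array.

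Male-biased genes of adult liver were above the mid-parent value in all 3 pairs, with both sexes weighted equally and neither tested alone. Of 17 tested, 14, 17 and 17 were higher and 0 lower for CAST and PWK, CAST and WSB, and PWK and WSB (15, 17 and 17 adjusted over the list alone), with medians of 0.52, 0.93 and 0.67. The adjusted p-values were 4.22e-24, 8.69e-39 and 6.24e-36 with camera, and 0.00291, 3.75e-05 and 8.43e-05 with an estimated correlation. For CAST and PWK, C6 was at 10.9 in the F1 (n = 21), level with PWK (10.91) and above CAST (8.56). Cyp2d9 and Mup20 lay 1.19 and 1.87 above the mid-parent value. Cyp7b1, a bile acid synthesis gene, was 1.54 above the mid-parent value for CAST and WSB and 1.37 for PWK and WSB, and Cyp4a12b 2.84 and 2.28. With the mid-parent value taken on the linear scale Cyp7b1 was 0.93 and 0.68 above it and Cyp4a12b 0.82 and 0.15, the last no longer called (adjusted p = 0.668). On that scale 13, 15 and 12 of the 17 were higher and 0, 1 and 0 lower, with medians of 0.36, 0.82 and 0.33. Of all liver genes, 16, 30 and 32 were then above the mid-parent value by at least 1 log2 unit in place of 48, 65 and 65, and 14, 18 and 6 below it in place of 8, 10 and 2. Of 18 tested female-biased genes 2, 4 and 0 were then higher and 12, 6 and 4 lower. On the log2 scale 2, 6 and 2 were higher and 12, 2 and 1 lower (14, 11 and 5 adjusted over the list alone). Medians were -0.41, 0.06 and 0.12, and adjusted p = 0.177, 0.638 and 0.456 with an estimated correlation. Genes of the kidney androgen-response list, which shares members with the male-biased list, were higher in liver for CAST and WSB and for PWK and WSB. In each pair 7 of 14 were higher and 2 lower (9 adjusted over the list alone), with adjusted p = 0.000874 and 0.00114 with an estimated correlation.

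**Figure D4:**
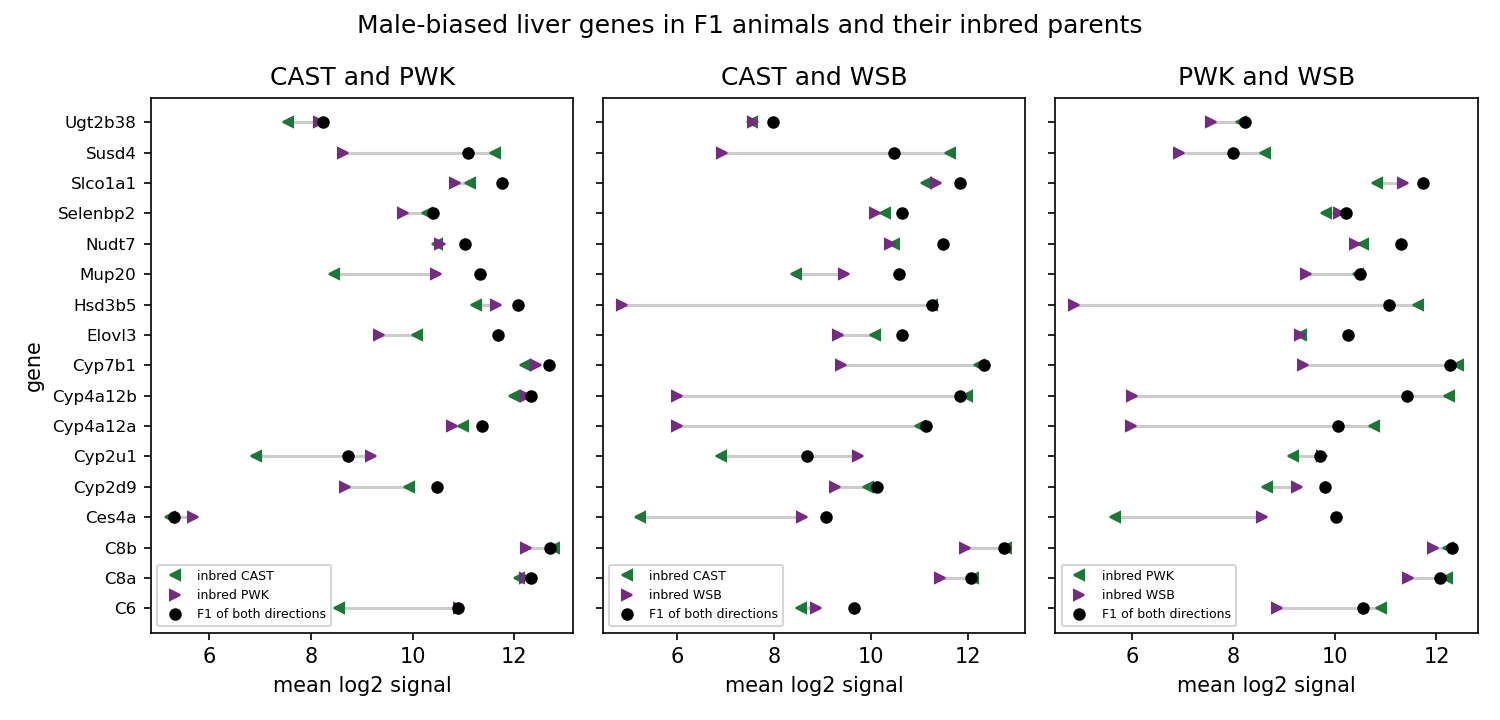
Liver signal (log2) of the 17 tested male-biased genes, as means of the inbred parents and of the F1 crosses for each pair of strains. The F1 means lie above the mid-parent value by medians of 0.52, 0.93 and 0.67 in the 3 pairs.

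Macrophage markers were below the mid-parent value in liver for PWK and WSB (9 of 12, 12 adjusted over the list alone, median -0.25, adjusted p = 0.0451 with an estimated correlation). Mpeg1 and C1qb differed by -0.25 each and Cd68 by -0.23. Proliferation genes were higher in liver for the same pair (23 of 24, 23 adjusted over the list alone), with Top2a at 1.37 and Ccna2 at 1.42. These genes had adjusted p = 0.0699 with an estimated correlation. Cholesterol synthesis genes were higher for CAST and WSB in liver (15 of 19, 16 adjusted over the list alone), with Sqle at 0.67 and Mvd at 0.94. The list had adjusted p = 0.129 with an estimated correlation. In brain, immediate-early genes were above the mid-parent value in 12, 16 and 7 of 21 (14, 16 and 11 adjusted over the list alone). Fos differed by 0.63, 0.95 and 0.38 in the 3 pairs and Arc by 1.06 for CAST and WSB. The list had adjusted p = 0.792, 0.0753 and 0.373 with an estimated correlation. Myelin genes were higher in brain for CAST and WSB (9 of 10, 9 adjusted over the list alone), with Mobp at 0.41. These genes had adjusted p = 0.811 with an estimated correlation. In kidney, interferon-response genes were lower for CAST and PWK (16 of 21, with 1 higher, 18 adjusted over the list alone). The list had adjusted p = 0.348 with an estimated correlation. Of the mid-parent list calls, 22 in brain, 21 in kidney, 44 in liver and 29 in lung were made at the preset correlation. Of these 0, 0, 6 and 0 held with an estimated correlation.

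Over all genes, 2138, 4187 and 1130 were called against the mid-parent value in brain, 3804, 4817 and 4220 in kidney, 2108, 2853 and 1924 in liver, and 2200, 3440 and 4196 in lung. Few were at least 1 log2 unit away outside liver (given above): 14, 28 and 15 higher in kidney and 12, 16 and 14 in lung, with 1, 2 and 2 and 4, 3 and 0 lower. On the linear scale, chosen after the data were seen, 1, 8 and 2 were higher and 2, 2 and 4 lower in kidney, and 0, 3 and 1 higher and 9, 4 and 2 lower in lung. More then lay below than above in all 3 pairs in lung and in both pairs with PWK in kidney. With runs of animal numbers as a random block, 935 and 436 genes were called in brain for CAST and PWK and for PWK and WSB. The counts were 959, 2039 and 1169 in kidney, 769, 1197 and 505 in liver and 667, 1528 and 1077 in lung. With levels of other-tissue marker lists as covariates, chosen after the data were seen, the brain counts for CAST and PWK and for CAST and WSB were 512 and 851, and with the lymphocyte covariate the lung count for PWK and WSB was 2698. Leaving out single brain arrays gave 1393 (CASTxCAST replicate 1) to 2689 (CASTxPWK replicate 4) for CAST and PWK. They gave 592 (PWKxPWK replicate 1) to 1268 (WSBxWSB replicate 10) for PWK and WSB.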

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

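Of the tests of explanations and of other groupings of the samples in this part, the comparison with random gene lists was written before its result was seen, and the others were chosen only after the result was seen.

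Between the reciprocal CAST and WSB crosses in lung 4381 genes were called, and 1099 with runs of animal numbers as a random block, while T and B cell markers were lower in CASTxWSB. Slopes on the level of 10 lymphocyte markers within the other crosses accounted for 62.1% of the squared differences of the called genes (57.2% to 65.7% with a cross left out) and gave the observed sign for 93.9%, so a lower share of lymphocytes in CASTxWSB lungs is a candidate explanation. Such slopes cannot separate lymphocytes from what varies with them: of 1000 random lists of 10 genes, 32 (3.2%) accounted for as much (median 17.2%, highest 76.6%), and with the level of the markers as a covariate 179 genes were called. Glucocorticoid target genes measured in the other tissues accounted for 29.5% (26.9% to 32%), and 2731 genes were called with their level as a covariate, so a part played by the glucocorticoid state of the animals cannot be told apart from the cross, whereas markers of muscle, fat and liver accounted for -5.2%. A difference between the directions of the cross itself was not tested apart from these and stays open.

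On 2 arrays Xist and the Y-linked genes went against the sex label. For the brain array of PWKxCAST replicate 9, labelled female, Eif2s3y at 3.827 excludes male tissue, since males of the cross were at 8.38 to 8.79. The mean of 4 X-escape genes was 10.13, against 10.42 to 10.50 in females and 10.04 to 10.09 in males of the cross, which is consistent with a brain with a single X chromosome, and the animal gave no other tissue, so whether this holds for the animal or only for this sample stays open. For the liver array of PWKxWSB replicate 8, labelled male, Eif2s3y at 4.53 and Xist at 10.70 are consistent with liver of another, female animal, as kidney and lung of the same animal were male by both genes. No partner out of place was seen, and the array nearest to it was WSBxPWK liver replicate 8, a female, with a correlation of 0.761 after centring, where the highest correlation of each liver array ranged from 0.467 to 0.843.

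X-linked expression of F1 females in lung lay nearer to the CAST parent for both pairs with CAST. F1 females lay 0.187 ± 0.0146 and 0.15 ± 0.0144 (SE) above the midpoint of F1 males. Females of PWK and WSB also lay 0.0744 ± 0.0223 (SE) above theirs, so it is not particular to pairs with CAST. It excludes neither effects that act in males too nor a curved array response. The SE covers F1 animals only, and both CAST pairs use the same 4 inbred CAST females, whose runs held no males. F1 males have only the dam's X, F1 females both. A few genes with a large strain difference are excluded as the whole cause, since without genes at least 2 log2 units apart the values were 0.135 ± 0.0457 (SD, n = 11) and 0.217 ± 0.0395 (SD, n = 12). An unequal choice of the active X chromosome that differs between animals may contribute: the score of F1 females, relative to the cross, correlated between tissues of the same animal with a mean Pearson r of 0.41 over 6 relations (0.34 to 0.51, n = 27 to 33), against -0.08 in F1 males. That relation bears on variation between animals and not on the mean shift toward CAST. For that shift no test separated a choice of the active X from other effects.

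The highest of the 6 relations in females was that of brain and lung, with r = 0.51 (permutation p = 0.0045), Spearman rho = 0.53 (permutation p = 0.0038) and an adjusted p = 0.018. Over the 6 relations the adjusted p ranged from 0.018 to 0.084, and without the 2 animals farthest from the median r was 0.19 to 0.46. In males r ranged from -0.17 to 0.10 with adjusted p-values of 0.79 to 0.86.

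Single arrays stood apart from their cross, sex and tissue in Xist in 5 of 69 groups and in the X-linked score in 3 of 47, where chance marks about 1 in 20. For Xist these were PWKxCAST brain female replicate 9 (3.98, others 9.78 to 10.46), PWKxPWK lung female replicate 9 (10.96, others 9.74 to 10.13), PWKxWSB liver male replicate 8 (10.7, others 3.79 to 4.8), PWKxWSB lung male replicate 9 (4.05, others 3.77 to 3.79) and WSBxWSB brain male replicate 6 (4.79, others 3.96 to 4.24). For the X-linked score they were WSBxCAST brain female replicate 7 (0.109, others -0.006 to 0.017), CASTxWSB lung female replicate 10 (0.248, others 0.141 to 0.176) and WSBxCAST lung female replicate 6 (0.239, others 0.135 to 0.166).

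The sex difference differed between crosses, by an interaction test, for 80 genes in brain, 510 in kidney, 918 in liver and 2630 in lung, and with runs of animal numbers as a random block for 26, 205, 196 and 155. The reciprocal difference differed between the sexes, for CAST and PWK, CAST and WSB, and PWK and WSB, for 6, 3 and 5 genes in brain, 14, 9 and 29 in kidney, 11, 11 and 12 in liver, and 12, 13 and 21 in lung.

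Other groupings of the same samples, 100 per comparison unless given, were used to ask whether chance can be excluded, and each count includes the real grouping. For the tissue difference 1 grouping gave as many genes (real counts 10691 to 10890, highest other 3376). For the inbred strains 1 grouping did in each of 12 comparisons (real counts 4562 to 7075, highest other 5836). For the mid-parent value 1 did, or 2 for PWK and WSB in liver (real 1130 to 4817, highest other 3786). For the reciprocal crosses 1 to 4 did (real 17 to 4381, highest other 1497), and the 4 were those of CAST and WSB in brain, with 88 genes in the real grouping and 729 in the highest other. For sex 2 did in brain, where the real count was 8 and the highest other 79, and 1 in kidney, liver and lung, with highest others of 1, 2 and 3. For sex by cross 2 did in brain (80 against 760) and 1 in kidney, liver and lung (highest others 102, 265 and 1321). For arrays taken as independent, chance is excluded at a share under 0.05 where no other grouping reached the real count. This leaves out the mid-parent value, whose groupings mixed parents with F1 animals. Groupings ignored the runs of animal numbers (consensus correlation 0.0876 to 0.256). With runs as a random block every reciprocal count fell (1052 to 10 in liver for CAST and PWK). So did counts of sex by cross (2630 to 155 in lung), most mid-parent counts and sex counts in kidney and lung. For these a chance difference between runs is not excluded.

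Within females the real count was 0 for 4 comparisons of reciprocal crosses, where every grouping is as large by construction and nothing about chance can be read from it. These were CAST and PWK in brain (87 of 87 groupings, highest other 0), PWK and WSB in brain (85 of 85, highest other 58), CAST and WSB in kidney (88 of 88, highest other 7) and PWK and WSB in kidney (86 of 86, highest other 94). With limma they had 349, 1282, 612 and 1186 genes at an unadjusted p under 0.05. In the other 8 comparisons of females 1 to 3 groupings of 67 to 93 gave as many, with a highest other of 162. Within males 1 to 3 of 64 to 94 did in 11 comparisons (highest other 3037), and 5 of 83 did for PWK and WSB in brain, where the real count was 17 and the highest other 2200, so chance cannot be excluded there. For the difference between the sexes the share was under 0.05 in 8 comparisons (CAST and WSB in lung real 13, highest other 1064). It was not in CAST and WSB in brain (6 groupings, real 3, highest other 358) and liver (5, 11, 296). Nor was it in PWK and WSB in kidney (5, 29, 434) and liver (5, 12, 484). Groupings with several times the real count, as 729 against 88 and 2200 against 17 in brain, point to a structure beyond cross and sex. A low share does not exclude chance there. The runs may follow this structure in part: with them as a block the brain count of 88 was 15.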

How the results depend on the processing

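The removal of single odd arrays (those with sex-linked genes against the label and 3 kidney arrays), the 3 kinds of covariate, the linear mid-parent value, the block for sex by cross and all tested genes for the X position were chosen after the data were seen, and the other settings before the data were examined. The filter on signals near background left out 40% of the genes per tissue, and without it all 18820 were tested. Of 1509 values under other settings of 72 results for genes named in strain and cross contrasts, 1472 kept direction and side of the threshold, 35 lost the call and 2 reversed. These 2 were 2610524H06Rik in brain for PWK and WSB (-0.021) and Chia1 in lung for CAST and WSB (-0.038), both with the linear mid-parent value. Among genes named for sex, Tceal6 in brain and Per2 in lung lost the call. Inbred counts stayed within 1.5 times under every setting except the 60th percentile filter. A renewed quantile normalisation moved 0 of 40 counts by over 1.5 times and leaving out 3 kidney arrays 0 of 11. The linear mid-parent value moved 0 of 12 (but 19 of 24 counts of genes at least 1 log2 unit away). The replicate block of the animal (tissue counts only) moved 0 of 4. Where a value moved the cause was not tested, except that a filter changes how many genes are tested and a left-out array lowers n.

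Pairs are given in the order CAST and PWK, CAST and WSB, PWK and WSB. With runs of animal numbers as a random block, 43 of 76 counts moved. Reciprocal counts were 6, 15 and 5 in brain, 5, 7 and 4 in kidney, 10, 38 and 5 in liver and 8, 1099 and 24 in lung, and mid-parent counts 935 and 436 in brain (first and last pair), 959, 2039 and 1169 in kidney, 769, 1197 and 505 in liver and 667, 1528 and 1077 in lung. Sex counts were 757 in kidney and 179 in lung. Within males reciprocal counts were 38, 22 and 17 in kidney, 45, 101 and 11 in liver and 26, 1623 and 40 in lung. Within females they were 0 in kidney for the first pair, 0, 0 and 3 in liver and 1, 2 and 2 in lung. The interaction for the last pair was 10 in kidney and 7 in liver, and sex by cross was 26 in brain, 205 in kidney, 196 in liver and 155 in lung (4 of 4 moved).

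With array weights 13 of 40 counts moved: reciprocal counts of 72, 481 and 388 in brain, 773 and 230 in kidney (first and last pair), 2285, 1211 and 483 in liver and 421 and 1568 in lung (first and last pair), and sex counts of 17 in brain, 2088 in kidney and 1028 in lung. In the additive model 5 of 40 moved, all reciprocal: 9 and 10 in brain (first and last), 71 in kidney (last), and 33 and 583 in lung (first and last).

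With the filter at the 60th percentile 11 of 40 moved: inbred counts of 2985, 3924 and 2897 in brain and 4578, 4474 and 4578 in lung, reciprocal counts of 53 and 12 in brain (second and last) and 42 and 553 in lung (first and last), and a mid-parent count of 1260 in liver (last). Without the filter 10 of 84 moved: tissue counts of 17486, 16621, 18011 and 17909 in brain, kidney, liver and lung, reciprocal counts within females of 1 in brain (last), 0 in kidney (first), 5 in liver (first) and 89 in lung (last), and interaction counts of 27 in liver and 33 in lung (last).

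With the glucocorticoid covariate 5 of 40 moved, all reciprocal: 11 and 9 in brain (first and second), 73 in kidney, 295 in liver and 2731 in lung (second). With the lymphocyte covariate 7 of 40 moved: reciprocal counts of 53 in brain (second), 45 in liver (last) and 133, 179 and 122 in lung, a mid-parent count of 2698 in lung (last) and a sex count of 127 in lung. With other-tissue covariates 7 of 40 moved: mid-parent counts of 512 and 851 (first and second) and a reciprocal count of 54 (second) in brain, reciprocal counts of 379 and 85 (second and last) and a sex count of 991 in liver, and a reciprocal count of 424 in lung (last). Without the arrays with sex-linked genes against the label 1 of 49 moved, the liver interaction of the last pair, to 33.

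Leaving out single arrays moved 29 of 559 counts. For brain mid-parent counts the range was 1393 (without CASTxCAST replicate 1) to 2689 (CASTxPWK replicate 4) for the first pair and 592 (PWKxPWK replicate 1) to 1268 (WSBxWSB replicate 10) for the last. For brain reciprocal counts it was 10 (CASTxPWK replicate 6) to 19 (CASTxPWK replicate 4) for the first pair, with 11 without CASTxPWK replicate 1. It was 29 (CASTxWSB replicate 5) to 122 (CASTxWSB replicate 8) for the second, with 38, 48 and 46 without CASTxWSB replicates 1, 4 and 7 and 55 and 58 without WSBxCAST replicates 4 and 8. It was 13 (PWKxWSB replicate 5) to 65 (PWKxWSB replicate 6) for the last, with 16, 15 and 15 without PWKxWSB replicates 3, 4 and 7. In kidney the reciprocal count of the last pair was 69 (WSBxPWK replicate 3) to 174 (WSBxPWK replicate 8), with 70 without WSBxPWK replicate 5. In lung it was 227 (PWKxWSB replicate 9) to 1521 (PWKxWSB replicate 8), with 424 without PWKxWSB replicate 1 and 296 without WSBxPWK replicate 10. The lung sex count was 189 (CASTxPWK replicate 4) to 817 (WSBxWSB replicate 11), with 240 without CASTxCAST replicate 2 or CASTxWSB replicate 7, 603 and 211 without PWKxWSB replicates 2 and 9, and 260 without WSBxWSB replicate 1.

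With an estimated correlation, list calls of 10, 22, 14 and 7 for inbred, mid-parent, reciprocal and sex contrasts in brain fell to 0, 0, 1 and 1, those of 6, 21, 30 and 11 in kidney to 0, 0, 1 and 3, those of 20, 44, 27 and 10 in liver to 1, 6, 1 and 4, and those of 7, 29, 41 and 18 in lung to 0, 0, 1 and 1. At 1 log2 unit or more sharing ratios were 21.53, 24.85 and 22.60.

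With weights from the other tissues the transmission score was called for X-linked genes in 7 comparisons of males, for maternally expressed genes in 1 of females and 2 of males and for paternally expressed genes in 3 of females (2 toward the sire and 1 toward the dam) and 2 of males. The X-linked minus autosomal score was then 0.0707 in kidney of the first pair, -0.0933 in kidney of the second and -0.085 in lung of the last (direction turned). For the X-linked genes alone fry gave an adjusted p = 0.00308 (now called), 0.0605 (no longer called) and 0.00237 (now called). Without genes with an inbred difference of at least 2 log2 units, autosomal genes were called in 0 comparisons of males (exact permutation test) and paternally expressed genes in 4, and the X-linked minus autosomal score was 0.127 in brain of the first pair (direction turned) and -0.0554 in kidney of the last. For the X-linked genes alone fry gave an adjusted p = 0.0494 (now called) and 0.116 (no longer called). With all tested genes of a class autosomal genes were called in 2 comparisons of males.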

Other observations

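The glucocorticoid target list, its relations between tissues and the listing of genes above both parents were chosen only after the data were seen.

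Glucocorticoid target genes varied together across the tissues of an animal. The mean of 8 such genes (Fkbp5, Tsc22d3, Zbtb16, Per1, Sgk1, Klf9, Ddit4 and Errfi1), taken relative to the cross and sex, correlated between each pair of tissues of the same animals with a Pearson r of 0.85 to 0.94 and a Spearman rho of 0.84 to 0.95 over 6 relations (n = 74 to 95). The permutation p was 1e-05 in each, the smallest the permutations can give, and without the 2 animals farthest from the median r was 0.83 to 0.93. In the reciprocal CAST and WSB crosses the list was higher in CASTxWSB with a median of 0.43 in lung (6 of 8 genes called), 0.37 in liver (4 of 8), 0.16 in brain (2 of 8) and 0.42 in kidney (1 of 8). With camera and an estimated correlation the p was 0.0771, 0.0056, 0.0143 and 0.017. It was also under 0.05 for PWKxWSB against WSBxPWK in brain (median 0.20, 1 of 8 genes called, p = 0.00553) and liver (0.32, none called, p = 0.0284), while it was 0.111 in kidney and 0.249 in lung. The median was above 0 in all 12 reciprocal contrasts, which are not independent, because the tissues came from the same animals.

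Other cell types were measured beside the main ones. Oligodendrocyte markers were highest in brain for 9 of 10 genes (median level 11.29) and astrocyte markers for 8 of 10 (11.23), airway markers were highest in lung for 11 of 12 (9.37), and markers of the distal nephron and collecting duct in kidney for 9 of 11 (11.27). T and B cell markers were highest in lung for 10 of 10 genes, with a median level of 7.31, and macrophage markers had medians of 8.79 in liver and 8.72 in lung. White fat markers were highest in kidney for 6 of 7 (9.11).

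Of the liver genes at least 1 log2 unit above the mid-parent value, 6, 15 and 9 were above both parents by at least 1 log2 unit for CAST and PWK, CAST and WSB, and PWK and WSB. Of the 17 male-biased genes 16, 13 and 16 lay within 1 log2 unit of the higher parent in the F1. In lung, T and B cell markers were above the mid-parent value for CAST and PWK (4 of 9 tested, 6 adjusted over the list alone, adjusted p = 0.575 with an estimated correlation), with Cd3e at 0.54, and proliferation genes for PWK and WSB (13 of 18, 14 adjusted over the list alone, adjusted p = 0.826 with an estimated correlation).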
